A study of Rattus norvegicus with 15 samples.

How the data were processed

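Gene expression was measured by RNA sequencing in 15 libraries of rat bone marrow mesenchymal stem cells, the adherent stromal cells of the marrow that can give rise to fat and bone cells. The deposited file was 1 table of read counts, unnormalised whole numbers per gene and library, with 34480 rows and 15 columns. Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0 were used with the genome build Rnor_6.0. The role and settings of each tool, the strand setting and the annotation release are not given in the sources used here. The table held 32883 rows with an Ensembl rat gene identifier and 1597 rows with names of another kind, whose origin is not given in the sources used here, and all rows named a feature. Whether reads shared between near-identical or overlapping genes were divided or dropped is also not given, so the values of such genes are uncertain. Each column name matched the title of a single sample, which gave its group and replicate number.

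The table pairs no identifier with a gene symbol. The gene table used here as a reference (assembly GRCr8) held 0 rat Ensembl identifiers, and 0 of the 34480 rows could be paired with a symbol. Genes are therefore given by identifier, without symbol, function or position. The 25 gene lists and the 15 core genes fixed before the data were examined could not be matched, and the tests of those lists were not run. The rule for genes to name had asked for the largest rises and falls among genes with an adjusted p under 0.05, no overlap between the 3 libraries of each group, at least 5 CPM in the higher group and a symbol. The symbol condition was dropped, Ensembl identifiers were required, and the first 2 in each direction are named.

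Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 5 groups, which left 15543 genes and over 99.9% of the counts in each library. Libraries were scaled by TMM, and all 15 libraries entered 1 quasi-likelihood model of group means (glmQLFit with robust estimation, glmQLFTest), with 6 contrasts and Benjamini-Hochberg adjustment over all genes kept, at a threshold of 0.05. Sharing 1 model lets all groups add to the estimate of the spread. The standard error of a log2 fold change was taken as its size divided by the square root of the test's F value. Levels are CPM values, edgeR's counts scaled by library size and TMM factor, as mean and SD of 3 libraries. Where a group had 0 counts in all libraries, the fold is a lower bound against 3 counts over that group, and where it had 1 to 3 counts the fold has an exact 95% interval for counting error only. Principal components were taken from log2 CPM with a prior count of 2.

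The counting depth was similar across libraries, with totals of 18373289 to 22817858 reads assigned to genes. Every pair of replicates differed by more than counting noise (chi-square per degree of freedom 5.41 to 13.5 over genes with at least 10 reads in the pair), so each library was counted as 1 replicate. Nothing in the labels says whether replicates were separate animals or separate dishes, so p-values measure the spread between these libraries, which may be technical. Deviations of libraries from their group means did not go together by replicate number (correlation -0.07 to 0.04 over 30 pairs of the same number), so the numbers were not taken to pair the libraries.

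Overlaps of calls between contrasts that share libraries were set beside the product n1 × n2 / N of independent lists and beside 20 simulated data sets with no difference between groups. A further 20 simulations kept the fitted medium effects and gave the fitted aspirin effects random directions, and 20 more put those effects on randomly drawn genes. Because the Adi group was shared between its comparison with Control and that with aspirin, both contrasts were also fitted with separate Adi libraries, 1 in the first contrast and the other libraries in the second or the reverse, which gave 6 assignments. The same was done with 1 Adi library left out and the others split. The simulations with random directions or random genes, all counts of calls with separate Adi libraries, the projection of libraries on the line from Control to a medium, the comparisons of aspirin-treated cultures with Control, the mean aspirin effect, the grouping of genes by the size of their change with the medium, the counts of detected genes and the directions of rows without an Ensembl identifier were chosen after seeing the data. The counts of calls with separate libraries replaced tests against those simulations whose outcomes had been read, and the closing section gives both. The model was tested on simulated data in which 200 genes with a mean of at least 1 CPM changed by known folds. Recovery of genes with fewer reads was not measured. For Adi_ASA versus Adi it recovered 10 of 50 genes changed 1.25-fold, 31 of 50 changed 1.5-fold, 42 of 50 changed 2-fold and 48 of 50 changed 4-fold. There were 7 false calls among the unchanged genes of the 15543. For Ost_ASA versus Ost it recovered 7, 27, 40 and 47 of 50 at the same folds, with 8 false calls.

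Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block and leaving out each library in turn. Leaving out the 20 most abundant genes and thinning every library to the smallest total were added after seeing the data.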

Results

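The study asked how aspirin acts on rat bone marrow mesenchymal stem cells that are driven towards fat cells or towards bone-forming cells. Aspirin (acetylsalicylic acid, written ASA in the group names) is an inhibitor of the cyclooxygenase enzymes. Cells of Sprague-Dawley rats, an outbred laboratory strain, were grown to confluence and fell into 5 groups of 3 libraries each. Control cells were untreated, Adi cells were kept in adipogenic differentiation medium, Adi_ASA cells in the same medium with aspirin, Ost cells in osteogenic differentiation medium and Ost_ASA cells in that medium with aspirin. The aspirin dose and the time in culture are not given in the sources used here. A change with a medium below is therefore a difference from Control that may include time in culture or batch. RNA sequencing gave 18373289 to 22817858 counted reads per library, and 15543 genes had enough reads to be tested. The count table pairs no identifier with a symbol, so genes are given by Ensembl identifier and their functions are not stated.

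The libraries separated first by medium. The first principal component of log2 CPM held 71.7% of the variance and set the 6 osteogenic libraries apart from the Control and adipogenic libraries. The second held 13.9% and set the adipogenic libraries apart from Control. On the second component, libraries with and without aspirin overlapped in adipogenic medium, and the Ost_ASA libraries (0.275 to 0.350) lay above the Ost libraries (-4.02 to -3.36). The next pair of components held 1.8% and 1.6% of the variance. On the third component, all Ost libraries lay above all Ost_ASA libraries and all Adi libraries above all Adi_ASA libraries. On component 4 the groups also separated by aspirin, in opposite directions in the media: Adi_ASA lay above Adi and Ost_ASA below Ost.

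**Figure D1:**
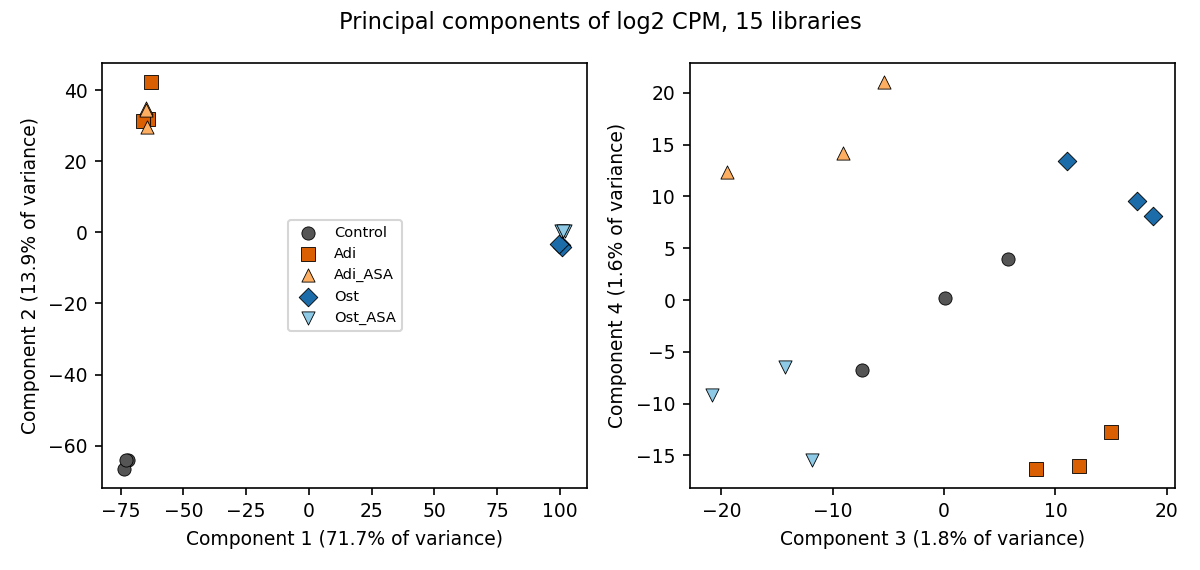
Principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM, each point 1 library, coloured by group, with the percent of variance on each axis. Medium separates the libraries on the first 2 components, and aspirin-treated and untreated libraries of each medium separate on the third, which holds 1.8% of the variance.

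Adipogenic medium was compared with untreated culture to show which genes change with adipogenic induction. Of the 15543 genes tested, 3810 rose and 3793 fell in Adi relative to Control (edgeR quasi-likelihood test, adjusted p under 0.05), which is 48.9% of the genes. At least 2-fold changes were found for 826 genes that rose and 1049 that fell, and at least 16-fold changes for 107 and 45. Among genes that met the rule for naming, ENSRNOG00000001001 rose from 0.0633 ± 0.0731 CPM (SD, n = 3) in Control to 90.7 ± 15.1 CPM in Adi (log2 fold change 10.42, SE 0.30, adjusted p = 5.16e-09). Its size rests on 4 reads in Control, and was 9.82 without Control replicate 1 and 11.66 without Control replicate 3. ENSRNOG00000009686 had 0 counts in all Control libraries and 7.65 ± 2.41 CPM in Adi, which is at least 170.5-fold higher (edgeR adjusted p = 4.71e-10). ENSRNOG00000037456 fell from 7.64 ± 0.788 to 0.0544 ± 0.0549 CPM, a 139-fold difference with a 95% counting interval of 47.2 to 676, since only 3 reads were counted in Adi (log2 fold change -6.97, and -7.84 without Adi replicate 2, edgeR adjusted p = 1.66e-09). ENSRNOG00000036672 fell from 39.2 ± 2.22 to 0.933 ± 0.18 CPM (log2 fold change -5.39, SE 0.15, adjusted p = 1.59e-16). The count of changed genes stayed between 6636 and 7613 under all alternatives run.

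Osteogenic medium was compared with the same untreated cells. More genes differed than in adipogenic medium, with 5314 higher and 5402 lower in Ost than in Control, or 68.9% of the genes tested (edgeR adjusted p under 0.05). Of these, 1970 rose and 2487 fell at least 2-fold, and 302 rose and 438 fell at least 16-fold. ENSRNOG00000029980 had 0 counts in Control and 147 ± 5.29 CPM in Ost, at least 3261-fold higher (edgeR adjusted p = 9.12e-22). ENSRNOG00000007680 likewise had 0 counts in Control and 74.9 ± 2.98 CPM in Ost, at least 1657-fold higher (edgeR adjusted p = 1.16e-18). In the other direction, ENSRNOG00000000010 had 154 ± 12.4 CPM in Control and 0 counts in Ost, at least 3319-fold lower (edgeR adjusted p = 9.66e-17). ENSRNOG00000007335 had 368 ± 24.4 CPM in Control and 0.0296 ± 0.0512 CPM in Ost, an 11983-fold difference with a 95% counting interval of 3317 to 98952, from 2 reads in Ost (edgeR adjusted p = 3.61e-11). Both reads were in Ost replicate 3, and without it the log2 fold change went from -13.29 to -15.89, a size that rests on the prior count. With aspirin, ENSRNOG00000029980 was at 161 ± 11.9 CPM and ENSRNOG00000007680 at 67 ± 6.56 CPM, and neither passed the test against Ost (edgeR adjusted p = 0.295 and 0.444).

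**Figure D2:**
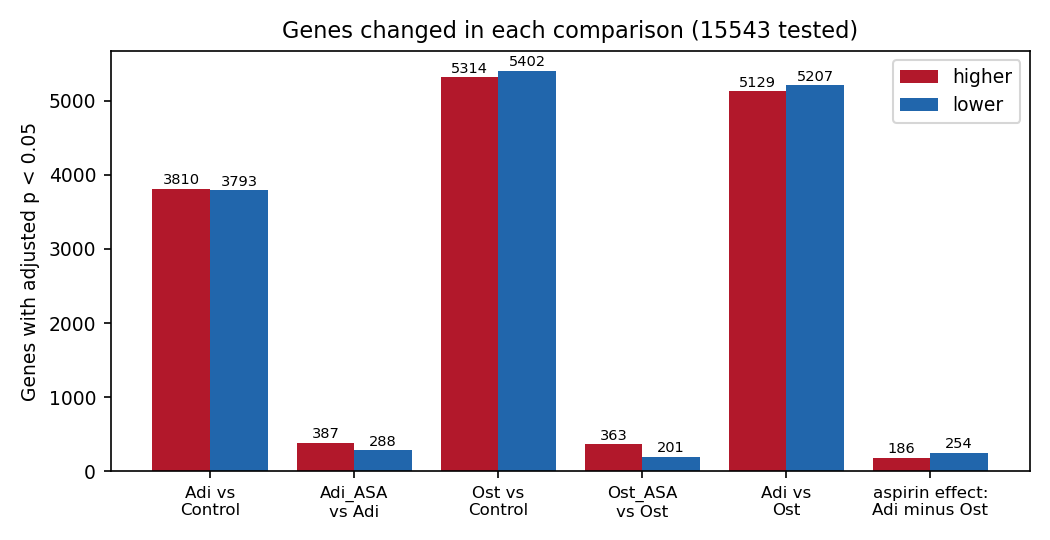
Number of genes (vertical axis) higher (red) and lower (blue) at an edgeR adjusted p under 0.05 in each comparison, and in the difference of the aspirin effects between the media. Adi and Ost differed from Control in 7603 and 10716 genes, and cultures with aspirin from those without in 675 and 564.

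The 2 media were compared directly and through their changes from Control. Between Adi and Ost, 5129 genes were higher in Adi and 5207 higher in Ost, and 2162 and 1855 of them differed at least 2-fold. ENSRNOG00000001821 reached 338 ± 75.4 CPM in Adi with 0 counts in Ost, at least 7339-fold higher in Adi (edgeR adjusted p = 7.42e-09), and was at 0.284 ± 0.251 CPM in Control. ENSRNOG00000001001 had 0 counts in Ost, at least 1968-fold lower than in Adi (edgeR adjusted p = 1.5e-09). ENSRNOG00000021924 had 12.8 ± 0.79 CPM in Ost and 0 counts in Adi, at least 233-fold higher in Ost (edgeR adjusted p = 5.64e-13), and ENSRNOG00000007680 had 1 read in Adi, which gives a 4093-fold difference with a 95% counting interval of 734 to 161685 (edgeR adjusted p = 2.62e-18). That read was in Adi replicate 1, and without it the log2 fold change went from -11.59 to -13.61, again resting on the prior count. Against Control, 2198 genes rose in both media and 2324 fell in both, where independent lists of the same sizes would share 1303 and 1318. Another 809 genes rose in Adi and fell in Ost, and 704 fell in Adi and rose in Ost. Both comparisons use the same Control libraries. Simulated groups with no difference shared 0.05 calls on average, and gave a correlation of log2 fold changes across genes of 0.49, against an observed 0.39. With no medium effect in them, these simulations cannot gauge what the shared Control libraries add to the counts of shared genes. The covariance was 0.70, against 0.048 in those simulations, a difference of 0.65. Part of the excess may come from the shared Control libraries, or from time in culture or batch if these set Control apart. Genes are not independent replicates.

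Aspirin was added to adipogenic medium to test its action on adipogenic induction. It changed 675 genes, 387 higher and 288 lower in Adi_ASA than in Adi, or 4.3% of the genes tested (edgeR adjusted p under 0.05), and 35 and 17 of them changed at least 2-fold. The balance of rises and falls varied with the method, with 429 higher and 429 lower under DESeq2 and 353 and 322 with RLE factors. ENSRNOG00000012302 rose from 2.78 ± 0.819 to 7.63 ± 0.7 CPM (log2 fold change 1.46, SE 0.14, adjusted p = 2.92e-06) and was at 66.9 ± 3.91 CPM in Ost. ENSRNOG00000023548 rose from 21 ± 7.73 to 52.7 ± 12 CPM (log2 fold change 1.33, SE 0.27, adjusted p = 0.0207), against 503 ± 38.5 CPM in Control. The genes named for their falls varied widely among the Adi cultures without aspirin. ENSRNOG00000050374 fell from 18.5 ± 11 to 1.34 ± 0.194 CPM (log2 fold change -3.78, SE 0.88, adjusted p = 0.0401) and ENSRNOG00000056428 from 5.1 ± 2.82 to 0.249 ± 0.146 CPM (log2 fold change -4.35, SE 1.00, adjusted p = 0.0391). These 2 falls lost their calls under 8 and 7 of the 13 alternatives, and the rise of ENSRNOG00000023548 under 3. The count of changed genes was 409 without Adi replicate 2, 414 without Adi replicate 3, and 437, 420 and 285 without Adi_ASA replicates 1, 2 and 3.

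Aspirin was likewise added to osteogenic medium. It changed 564 genes, 363 higher and 201 lower in Ost_ASA than in Ost, or 3.6% of the genes tested, and 42 and 29 of them changed at least 2-fold. ENSRNOG00000022432 rose from 2.04 ± 0.107 to 6.9 ± 0.27 CPM (log2 fold change 1.76, SE 0.17, adjusted p = 3.46e-06). ENSRNOG00000055012 rose from 6.55 ± 3.63 to 34.1 ± 14.3 CPM (log2 fold change 2.37, SE 0.50, adjusted p = 0.0287). ENSRNOG00000001189 fell from 35.6 ± 9.47 to 12.4 ± 2.73 CPM (log2 fold change -1.52, SE 0.24, adjusted p = 0.00592), and ENSRNOG00000051591 fell from 17.3 ± 15.6 to 1.16 ± 0.371 CPM (log2 fold change -3.89, SE 0.78, adjusted p = 0.021). Of the 13 alternatives, ENSRNOG00000055012 lost its call under 6, ENSRNOG00000051591 under 5 and ENSRNOG00000001189 under 1. The fall of ENSRNOG00000051591 was -2.99 without Ost replicate 1 (edgeR adjusted p = 0.0507). The count of changed genes was 338 without Ost replicate 1, 347 without Ost replicate 2 and 370 without Ost_ASA replicate 3.

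The genes changed by aspirin were set beside those changed by the medium. In adipogenic medium, 591 of the 675 genes changed by aspirin had also changed with the medium (87.6%), and in osteogenic medium 503 of 564 (89.2%). In 20 simulations that kept the libraries shared and put the aspirin effects on randomly drawn genes, the shares were 45.2% to 56% and 67.4% to 77.3%. Those simulations did not match the drawn genes for read counts, and they called 265.3 and 249.9 genes with aspirin on average, against 675 and 564, so their lists were shorter than those observed. In adipogenic medium, 444 of the 591 moved back towards Control with aspirin and 147 moved further away. Independent lists would give 165 of each. Of the genes raised by the medium 220 fell with aspirin, with a median log2 fold change of 0.76 for the medium and -0.32 for aspirin. Of those lowered by the medium 224 rose, with medians of -0.92 and 0.41. In Adi_ASA, 164 and 144 of these genes still differed from Control in the direction of the medium. Both comparisons use the Adi libraries, and 20 simulations with aspirin effects of random direction gave 48.9% to 56% opposite directions, against 75.1% observed, but called only 316.5 genes in both on average, against 591. The covariance of the log2 fold changes across genes was -0.104, against -0.049 in simulated groups with no difference and -0.063 in simulations with the medium effects kept and no aspirin effect. In osteogenic medium it was also negative, at -0.078 against -0.049 and -0.070, but on log2 CPM values it went from -0.025 with shared Ost libraries to 0.00797 ± 0.00434 (SD over 6 assignments) with separate ones, and was positive in all 6. The counts back and further were 374 and 94 without Adi replicate 1, 275 and 81 without Adi replicate 2 and 203 and 140 (59.2% opposite) without Adi replicate 3. They were 287 and 97, 266 and 102, and 154 and 95 (61.8%) without Adi_ASA replicates 1, 2 and 3. With separate Adi libraries in the 2 comparisons it ranged from 38.1% to 85.4% over the 6 assignments, with a mean of 64.5% ± 18.3 (SD), and it was 49.4% and 39.6% when Adi replicate 3 was left out and the other Adi libraries were split. The same split gave 85.3% and 51.4% without Adi replicate 1 and 84% and 41.4% without Adi replicate 2, so over these 12 assignments it was 76.2% to 85.4% in the 5 with Adi replicate 3 in the aspirin comparison and 38.1% to 54.5% in the other 7, a division seen after the values were read.

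The distance of each library from Control over all genes was measured next, a comparison chosen after seeing the data. Libraries were projected on the line from the Control mean, at 0, to the mean of the 6 adipogenic libraries, at 1. The Adi libraries lay at 1.01 ± 0.0578 (SD, n = 3) and the Adi_ASA libraries at 0.991 ± 0.026, a difference of -0.018 that was smaller than the spread between libraries (exact permutation test, two-sided, p = 0.8). Adi replicate 3 lay at 1.076 and Adi replicates 1 and 2 at 0.979 and 0.972, against 0.961 to 1.009 in Adi_ASA. On the corresponding line for osteogenic medium, Ost lay at 0.995 ± 0.00266 and Ost_ASA at 1.01 ± 0.00417 (exact permutation test, two-sided, n = 3, p = 0.1, the smallest value that 3 libraries against 3 allow). Of the 503 genes changed by osteogenic medium and by aspirin, 262 moved further from Control and 241 moved back, against 194 and 195 for independent lists. The 20 simulations with aspirin effects of random direction gave 45.6% to 56.1% opposite directions, against 47.9% observed, with 301.2 genes called in both on average, against 503. The further group comprised 185 genes raised and 77 lowered by both. The counts back and further were 151 and 154 without Ost replicate 1, 153 and 161 without Ost replicate 2, and the count back was 160 without Ost_ASA replicate 3.

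**Figure D3:**
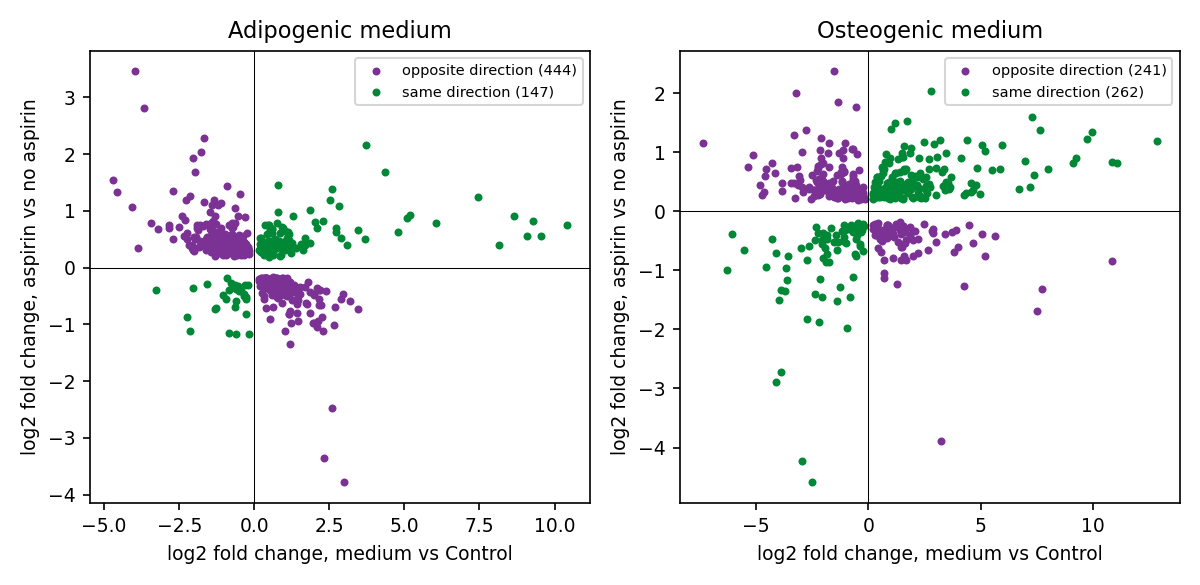
Log2 fold change with aspirin (vertical axis) against log2 fold change with the medium (horizontal axis) for genes with an adjusted p under 0.05 in both comparisons, adipogenic medium on the left and osteogenic on the right, each point 1 gene; extreme values of genes with 0 counts in a group depend on the prior count. In adipogenic medium 444 genes lie in the opposite quadrants (purple) and 147 in the same-direction quadrants (green), and in osteogenic medium 241 and 262.

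The aspirin effects in the 2 media were then compared with each other. These 2 contrasts have no library in common, although the spread of each gene was estimated from all 15 libraries. For 89 genes the effect passed the test in both media. They moved in the same direction for 52 genes, 32 higher and 20 lower, and in opposite directions for 37, where independent lists would give 12.8 and 11.7. With 1 spread estimate per gene in both tests, calls can coincide more often than in independent lists. The excess in both directions therefore does not by itself show linked effects of aspirin. DESeq2 gave 76 in the same direction and 62 in opposite directions (44.9% opposite, against 41.6%). Without Adi replicate 3, Adi_ASA replicate 2 and Adi_ASA replicate 3 those in opposite directions were 21, 22 and 21, and without Adi_ASA replicates 1 and 3 those in the same direction were 34 and 27. Across genes the correlation of the 2 log2 fold changes was 0.04. The difference of the effects itself passed the edgeR test for 440 genes, with 186 more positive and 254 more negative in adipogenic medium. Of the 440 genes, 177 were changed by aspirin in adipogenic medium alone, 167 in osteogenic medium alone, 38 in both and 58 in neither. The mean aspirin effect over both media, a contrast added after seeing the data, passed the test for 759 genes, 481 higher and 278 lower. ENSRNOG00000022432 rose 1.76 on the log2 scale in osteogenic medium and had -0.36 (SE 0.17) in adipogenic medium, where it did not pass the test (edgeR adjusted p = 0.268). The difference for this gene was -2.12 (SE 0.24, adjusted p = 2.66e-05), and it passed the test under all 19 alternatives. Without Adi_ASA replicate 3, the number of genes with different effects was 289.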

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

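Chosen only after results had been seen were the tests on positions along the line from Control, on genes at 0 counts and on the counts in each direction as a sign of scaling, both tests of the genes moved back that split the Adi libraries, which replaced earlier tests whose outcomes had been read, and the simulated covariance on the log2 CPM scale; thinning was added after seeing the data, with its bound set before its result.

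A difference between the media in the effect of aspirin, tested as an interaction, was found for 440 genes. Among the identifiers named by rule were ENSRNOG00000017539, at 3.41 (SE 0.59, edgeR adjusted p = 0.00232), and ENSRNOG00000049695, at 2.28 (SE 0.47, adjusted p = 0.00817), both on the log2 scale as adipogenic minus osteogenic. ENSRNOG00000022432 stood at -2.12 and ENSRNOG00000055012 at -3.14 (SE 0.69, adjusted p = 0.0374). The value of ENSRNOG00000017539 rests on 15 reads in Ost and 2 in Ost_ASA, and that of ENSRNOG00000049695 on 6 reads in Adi and 27 in Adi_ASA. ENSRNOG00000017539 lost its call without Ost replicate 3 (2.94, edgeR adjusted p = 0.0723, range over the 19 alternatives 0.00176 to 0.0723), and ENSRNOG00000049695 without Adi replicate 2 (1.72, edgeR adjusted p = 0.0837, range 0.00305 to 0.0837), while without Adi replicate 3 its value was 3.19. Over the 19 alternatives the adjusted p of ENSRNOG00000055012 ranged from 0.000222 to 0.101 and it lost its call under 11.

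Expression in 1 medium only is argued against for most of the 440 genes, since 4.32% of them lay under 1 CPM in a medium. The share over all genes tested was 18.7%, but genes with few reads are seldom called, so the lower share is no test. Of the named genes, ENSRNOG00000017539 lay under 1 CPM in osteogenic medium (0.225 in Ost, 0.0295 in Ost_ASA). So did ENSRNOG00000049695 in adipogenic medium (0.109 in Adi, 0.471 in Adi_ASA). A dependence on a single library stays open in part. Without Adi_ASA replicate 3 the count was 289, past the bound of 1.5 times set in advance, although 278 of those were among the 440. Of 50 regroupings of the libraries within each medium, 2 gave as many genes, the real one included. The other one, with 759 genes, was the exchange of the aspirin labels in 1 medium, which measures the mean aspirin effect, and the highest of the remaining regroupings gave 88. Those remaining regroupings mix libraries with and without aspirin, which adds the aspirin effect to the spread within groups. Few calls would follow with or without a difference between the media, so these counts cannot exclude chance for the difference. A difference in what aspirin does in the 2 media is the biological explanation that the design offers, and it was not tested apart from this contrast.

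The excess of genes that moved back towards Control with aspirin in adipogenic medium (444 against 147) was weighed next. A shift in scaling set by a few abundant genes would move all genes one way. It could not alone give both the 220 raised genes that fell and the 224 lowered genes that rose. TMM centres the fold changes, so the near balance of these counts does not test scaling as part of the cause. With RLE factors, which put the aspirin calls at 353 higher and 322 lower, 446 genes moved back and 145 further. Leaving out the 20 most abundant genes (440 moved back) changed the counts of calls too little to test scaling. The shared Adi libraries were first tested against 20 simulations with random directions of the aspirin effects, whose highest value of 56% lay under the 75.1% observed, and a single Adi library by leaving each out, with a lowest value of 59.2%, also above 56%; both first outcomes spoke against these explanations, but the simulations called 316.5 genes in both on average against 591, and a bound from simulations excludes nothing, and the tests were replaced. With separate Adi libraries the mean of 64.5% ± 18.3 (SD over 6 assignments) joins 2 distinct sets, since with the splits of 2 libraries added it was 76.2% to 85.4% in the 5 assignments with Adi replicate 3 in the aspirin comparison and 38.1% to 54.5% in the 7 without it there, 39.6% being the lower of 2 splits with that library left out, so the excess followed the place of 1 library, picked after seeing the values, a single Adi library could account for it, and whether the shared libraries add to it cannot be told. Whether dishes differed in how far they moved from Control, apart from aspirin, stays open. The positions of Adi and Adi_ASA libraries overlapped and their means differed by -0.018, which decides nothing for these genes. Adi replicate 3 lay furthest from Control, at 1.076. Adi replicates 1 and 2 lay at 0.979 and 0.972, and the Adi_ASA libraries at 0.961 to 1.009. The excess followed the place of Adi replicate 3, so a single library and a difference between dishes cannot be told apart here. An effect of aspirin itself stays open too.

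Over all genes, on log2 CPM values, the covariance of the same pair of effects was -0.061 with shared Adi libraries, -0.039 in simulated groups with no difference and -0.024 ± 0.0253 (SD over 6 assignments) with separate Adi libraries. The separate-library values were negative in all 6 assignments (-0.0656 to -0.00155), the most negative with Adi replicate 3 alone in the aspirin comparison. A bound of 0.5 times the simulated value had first been set against simulated fold changes of another scale, where it was narrowly met. On the same scale it was not met, and the separate-library values did not lie below 0 by more than 2 SD, so for this covariance the shared libraries and an effect of aspirin cannot be told apart.

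The share of genes changed between Ost and Control (10716 of 15543) was the third pattern. Depth is argued against by the totals, which overlapped at 19605404 to 22817858 in Control and 18373289 to 22543679 in Ost. With every library thinned to the same total 10613 genes changed. Totals this close leave thinning little to remove, so that count adds little as a test. A shift in scaling set by a few abundant genes would move all genes in the same direction. It could not alone give both the 1970 genes that rose and the 2487 that fell at least 2-fold. TMM centres the fold changes (median log2 fold change over all genes tested -0.023). The near balance of rises and falls therefore does not test scaling as part of the cause. Cells of another stock or batch in the osteogenic cultures cannot be told apart from an effect of the medium, since all 6 osteogenic libraries may share both. There were 3 genes at 0 counts in every library of one kind and at least 5 CPM in every library of the other, 2 of them on the osteogenic side, which either explanation would allow, and the medium effect named by the design was not tested separately.

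With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the most genes in each comparison. It gave 7603 genes for Adi versus Control, 10716 for Ost versus Control and 10336 for Adi versus Ost, with a highest other split of 0 in each. It gave 675 for Adi_ASA versus Adi and 564 for Ost_ASA versus Ost, with a highest other split of 1 in each.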

How the results depend on the processing

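The alternatives that leave out the 20 most abundant genes or thin the libraries, and all overlaps under RLE factors or with a library left out, were added after seeing the data. With all 15 libraries, every count of changed genes stayed within 1.5 times of its value under DESeq2, RLE factors, no low-count filter, a fit of the compared groups alone, the replicate block, thinning and without the 20 most abundant genes. The replicate block gave 7481 genes for Adi versus Control, 572 for Adi_ASA versus Adi, 10615 for Ost versus Control, 516 for Ost_ASA versus Ost, 10224 for Adi versus Ost and 404 for the difference of aspirin effects; the numbers do not pair the libraries, and 0 of 15 libraries correlated best with one of its own number. DESeq2 gave 62 genes with opposite and 76 with the same direction of aspirin effects in the media, against 37 and 52. Each library of the groups compared was left out in turn. Counts then ranged from 6636 to 7037 for Adi versus Control, 285 to 538 for Adi_ASA versus Adi and 10187 to 10264 for Ost versus Control. They ranged from 338 to 543 for Ost_ASA versus Ost, 9719 to 9882 for Adi versus Ost and 289 to 428 for the difference of aspirin effects. Overlaps were ranged over the libraries of the groups in each pair. Genes changed by adipogenic medium and aspirin ranged from 154 to 416 in opposite and 81 to 140 in the same direction. Those for osteogenic medium ranged from 151 to 245 and 154 to 261. Genes changed by both media ranged from 1259 to 1492 and 3991 to 4407, and those changed by aspirin in both media from 21 to 36 and 27 to 61. Leaving out a library of another group also moved these overlaps. Without Ost_ASA replicate 3 they were 514 and 163 for adipogenic medium and aspirin, and 1567 and 4639 for both media. Without Adi replicate 3 those for osteogenic medium and aspirin were 256 and 284. Every such setting has 1 library fewer, which can lower the counts of changed genes. The counts also depended on which library was left out. Adi_ASA versus Adi gave 285 genes without Adi_ASA replicate 3 and 538 without Adi replicate 1. Of 336 alternative values for the 24 named fold changes, 293 kept their direction and call, 43 kept their direction and lost the call, and 0 reversed. The list tests and their alternatives were not run. At this depth and spread, aspirin effects under 1.5-fold were often missed, since the simulated recovery was 31 and 27 of 50 at that fold. Those simulated genes had a mean of at least 1 CPM, and recovery below that level was not measured.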

Other observations

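The test on strongly induced genes, noticed in a plot of the same data, and the values on detected genes, the most abundant gene and the rows without an Ensembl identifier were chosen after seeing the data.

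Of the 107 genes that adipogenic medium raised at least 16-fold, 12 rose further and 0 fell in Adi_ASA relative to Adi. Among the 219 genes raised 4 to 16-fold 12 rose and 22 fell, among the 500 raised 2 to 4-fold 19 rose and 43 fell, and among the 2984 raised less 74 rose and 155 fell. The difference between these groups of genes was not tested. In osteogenic medium more genes rose than fell with aspirin in every such group, with 29 and 10 of the 302 genes raised at least 16-fold, 40 and 15 of the 631 raised 4 to 16-fold, 53 and 33 of the 1037 raised 2 to 4-fold and 63 and 37 of the 3344 raised less. Genes lowered by osteogenic medium leaned the same way (10 and 8, 46 and 23, 46 and 21, 44 and 25, largest falls first). Over all calls with aspirin in that medium 363 rose and 201 fell, so the lean was not particular to raised genes. Genes lowered by adipogenic medium also rose more often than they fell (4 and 0, 24 and 4, 74 and 4, 122 and 22). With each library of the aspirin comparisons left out in turn, calls higher with aspirin among genes raised at least 16-fold were at least 2.33 times the calls lower, but in adipogenic medium the calls lower were mostly 0 and the genes had been picked for this pattern, so a single library as its source was not excluded. The adipogenic counts were 7 and 0 without Adi replicate 1, 4 and 1 without Adi replicate 2, 15 and 0 without Adi replicate 3, and 5 and 0 without each Adi_ASA library. The mean log2 CPM of the 107 genes was 2.09 ± 0.25 (SD, n = 3) in Adi and 2.40 ± 0.10 in Adi_ASA, with 2 of 3 Adi_ASA libraries above all Adi libraries (exact permutation test, two-sided, n = 3, p = 0.2, where 0.1 is the smallest possible value). For the 302 genes in osteogenic medium it was 3.48 ± 0.05 without and 3.57 ± 0.00242 with aspirin (exact permutation test, two-sided, n = 3, p = 0.1, the smallest possible value).

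The gene with the most reads in the Adi libraries, ENSRNOG00000003897, took 3.71% ± 0.0194 of the counts in Control (SD, n = 3), 6.64% ± 0.176 in Adi and 5.66% ± 0.289 in Adi_ASA. In Ost it took 0.136% ± 0.0118, which is 27.3-fold lower than in Control, and in Ost_ASA 0.162% ± 0.0101. The 20 most abundant genes together took 21.4% ± 0.398 of the counts in Adi, 13.1% ± 0.123 in Control and 10.6% ± 0.261 in Ost.

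Against Control, changed rows without an Ensembl identifier fell in larger part than those with one in both Adi and Ost. Of the 1333 such rows tested, 186 rose and 303 fell in Adi relative to Control (38% of the changed ones rose, against 50.9% of rows with an Ensembl identifier; Fisher's exact test across genes, two-sided, adjusted p = 9.28e-08 over 6 contrasts). In Ost, 319 rose and 529 fell (37.6% against 50.6%, adjusted p = 1.82e-12). Between Adi and Ost, 56.6% of them were higher in Adi, against 49% (adjusted p = 7.69e-05). With aspirin 10 rose and 13 fell in adipogenic medium (43.5% against 57.8%, adjusted p = 0.200) and 21 rose and 6 fell in osteogenic medium (77.8% against 63.7%, adjusted p = 0.185), and the difference of the aspirin effects had 2 and 10 (adjusted p = 0.121), none of which passed the test. Genes are not independent replicates. These rows held 0.841% ± 0.0307 of the counts in Control, 0.695% ± 0.0302 in Adi and 0.691% ± 0.0176 in Ost (SD, n = 3).

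With every library thinned to the same total, 18660 ± 88.5 genes had at least 1 read in Adi_ASA and 18516 ± 106 in Adi (SD, n = 3; exact permutation test, two-sided, p = 0.2). In osteogenic medium it was 18278 ± 17.8 with and 18150 ± 82.5 without aspirin, higher in 3 of 3 libraries (exact permutation test, two-sided, n = 3, p = 0.1, the smallest possible value).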
